A study of Mus musculus with 16 samples.

How the data were processed

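RNA was sequenced from mouse cardiac tissue of 4 genotypes, with 4 libraries per genotype: wild type, knockout of Fgf21, knockout of Clpp, and knockout of both genes. The labels state that deletion was whole-body, by Cre recombinase driven from the β-actin promoter. They give each library a repeat number and do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may in part be technical.

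The deposited table holds counts per gene for the 16 libraries. Per the submitters' processing notes, reads were handled with fastp 0.21.0 and kallisto 0.46.1 on the genome build GRCm38.p6, and edgeR 3.32.1, DESeq2 1.30.1 and R 4.0.3 were also used. kallisto assigns a read that matches several transcripts in shares, so its estimated counts need not be whole. The deposited counts are whole numbers, and the step that made them whole is not given in the sources used here. Reads that match a gene and a near-identical copy are shared between both, which can move counts from one to the other. Counting by strand is not stated, so overlapping and antisense genes cannot be told apart.

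Of 36499 gene entries in the table, 24625 held a count in at least 1 library. Totals ran from 36260545 to 51820727 counts per library. A symbol stood on more than 1 entry for 440 symbols, and 550 gene identifiers were absent from the GENCODE M21 annotation of GRCm38, which gave all coordinates. Counts were tested as deposited.

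Genes were kept by the filterByExpr function of edgeR 4.0.16 with a count minimum of 10 and a total minimum of 15, which left 15255 genes. Libraries were scaled by TMM (trimmed mean of M-values), with factors from 0.674 to 1.83. One edgeR quasi-likelihood model with robust dispersion was fitted to all 16 libraries, with 12 residual degrees of freedom and a common biological coefficient of variation of 0.249. The 6 comparisons were Clpp KO against wild type, Fgf21 KO against wild type, double KO against each single KO, double KO against wild type, and the interaction, meaning the effect of Fgf21 loss without CLPP minus its effect with CLPP. Tests were two-sided, and adjusted p-values follow Benjamini and Hochberg over all genes tested, with a threshold of 0.05. A gene is called here when it passed that threshold. Levels in CPM are counts scaled to a common library total alone, while log2 CPM, list scores and fold changes are scaled by TMM, so ratios of CPM differ from fold changes. Errors after ± are standard errors for log2 fold changes and SD over libraries for levels. R 4.3.3 was used.

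The design, the tests, the rule for named genes and 47 gene lists were fixed before the data were examined. Of these lists 16 hold markers of cell types or tissues. The rule names Clpp and Fgf21, then the 8 genes with the largest positive and the 8 with the largest negative fold change among called genes. These needed a mean of at least 1 CPM scaled by TMM over all libraries and no overlap between the groups, and gene models without a symbol of their own were left out. From each list it names up to 4 called members with the smallest p, or 2 where none was called. For a comparison with no called gene it names the 5 genes with the smallest p. A gene named outside the rule is said to have been chosen after its values were seen.

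Lists were tested with camera from limma 3.58.1, which asks whether the members of a list rank apart from all other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. The same test with an estimated correlation and fry, which asks whether the members of a list move 1 way on balance, were alternatives. Counts "adjusted over the list alone" apply Benjamini-Hochberg to the members of that list. Shares of counts and levels of genes under the filter were compared by exact two-sided permutation tests, whose smallest p with 4 libraries against 4 is 0.0286. Intervals for counts are exact Poisson intervals at 95%, and a gene with 0 counts was given a floor of 3 counts; both cover counting error only, since reads without molecular identifiers are not independent molecules.

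The steps were tested on simulated counts for the 15255 genes, with changes of known size added. In Clpp KO against wild type the simulation recovered 79.1% of 2-fold changes, in Fgf21 KO against wild type 73.1%, in double KO against Clpp KO 68.7%, in double KO against Fgf21 KO 64.2% and in double KO against wild type 62.7%. For 1.5-fold changes the same shares were 20.9%, 20.9%, 19.4%, 22.4% and 23.9%. For 4-fold changes they were 89.4%, 92.4%, 89.4%, 78.8% and 89.4%. Each share rests on 66 or 67 changed genes in a single simulated set, so differences between these comparisons may be sampling alone. The interaction recovered 0% of 1.5-fold, 35.8% of 2-fold and 71.2% of 4-fold changes. False calls made up between 0.8% and 6.6% of the calls. Among lists of 20 genes, camera found 10 of 10 raised by 1.5-fold and called 1 of 10 that were not changed. These rates hold for the simulated counts. When the Fgf21 KO and wild-type libraries were assigned to other groups than their own, up to 35 lists passed and up to 1023 genes were called. False calls may therefore be more frequent in these libraries than in the simulation.

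Alternatives were other scalings, other filters, DESeq2 1.42.0, limma voom with quality weights, a fold minimum of 1.2, a threshold of 0.01, a fit to the groups compared alone, the repeat number as a block, sex as a covariate, and leaving out each library. After the data were seen, further alternatives were added: leaving out wild-type replicates 2 and 4, summing wild-type replicates 1 and 3, 1 entry per symbol, and a covariate for atrial transcripts (the mean log2 CPM of Myl7, Myl4 and Sln). Read sharing between genes was estimated from GENCODE M21 transcripts as the share of a gene's 31-mers that also occur in another gene. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for joins, single values and figures.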

Results

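Gene expression in mouse cardiac tissue was compared between wild-type mice and mice lacking Fgf21, Clpp or both genes. CLPP is the proteolytic subunit of ClpXP, a protease of the mitochondrial matrix, and FGF21 is a secreted hormone that tissues under mitochondrial or nutritional stress can release. The series title asks whether FGF21 changes the cardiac response to mitochondrial stress when the dysfunction is mild. Each genotype had 4 libraries, with 36260545 to 51820727 counts per library.

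Clpp lies on chromosome 17, positions 56990305 to 56996188 of GRCm38 (ENSMUSG00000002660). Its counts were 1728, 1912, 1807 and 2108 in wild type and 2636, 1910, 2007 and 1435 in Fgf21 KO. In Clpp KO they were 333, 336, 355 and 308, and in double KO 272, 267, 289 and 293. Mean levels of Clpp were 46.4 ± 10.5 CPM in wild type, 45.1 ± 9.11 in Fgf21 KO, 7.08 ± 0.509 in Clpp KO and 6.11 ± 0.238 in double KO (SD, n = 4 each). Clpp reads therefore fell in every library labelled as lacking Clpp and did not reach 0. The counts are summed over the gene, and which exons the remaining reads came from was not analysed here.

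Fgf21 lies on chromosome 7, positions 45613886 to 45615490 (ENSMUSG00000030827). It had 0 counts in all 8 libraries labelled as lacking Fgf21. Wild-type replicates held 1, 0, 5 and 0 counts, and Clpp KO replicates 21, 6, 28 and 14. Fgf21 was thus near the detection limit in wild-type hearts and was present in each Clpp KO library, at 0.356 ± 0.17 CPM against 0.0312 ± 0.0489 CPM (SD, n = 4 each, exact two-sided permutation test p = 0.0286, the smallest it can give). The ratio of pooled counts for Fgf21 was 10.1 by library totals (95% counting interval 4.43 to 28.6) and 16.8 with totals scaled by TMM, as for fold changes (7.36 to 47.5). Against double KO, with a floor of 3 counts over the group, Fgf21 in Clpp KO was at least 22.3-fold higher by library totals and at least 20.0-fold by TMM. Fgf21 was too low for the test across all genes.

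**Figure D1:**
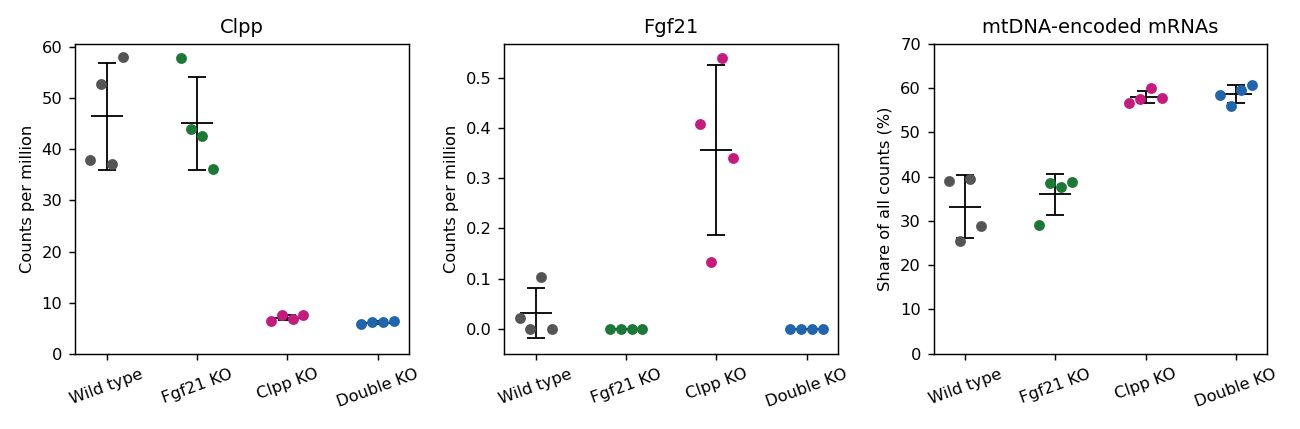
Clpp and Fgf21 (CPM) and the share of counts from mtDNA-encoded mRNAs (%) in each of the 16 libraries, as dots, with group means and SD as bars. Clpp was at 6.11 to 7.08 CPM on average in the groups lacking it, Fgf21 was detected mainly in Clpp KO, and the mtDNA share was above 56% in the libraries lacking Clpp.

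The wild-type libraries did not form 1 homogeneous group. Myl7, the atrial myosin light chain, stood at 3160 and 1800 CPM in wild-type replicates 2 and 4 and at 1.45 and 1.40 CPM in replicates 1 and 3. Nppa, which encodes atrial natriuretic peptide, followed the same division with 10700 and 4620 against 89.5 and 83.6 CPM. Ucp1, the brown fat uncoupling protein, reached 3.75 and 29.9 CPM in replicates 2 and 4 and at most 0.0657 in replicates 1 and 3. In the knockout groups Ucp1 was at 2.34 CPM in Fgf21 KO replicate 4, 2.0 in Clpp KO replicate 1 and at most 0.0459 elsewhere. Myl7 in the other 12 libraries ran from 0.195 CPM in double KO replicate 4 to 587 CPM in Fgf21 KO replicate 4. Wild-type replicate 2 had 0.221 CPM from Y-linked genes, where the other libraries had 39.4 to 71.0. Wild-type replicates 1 and 3 were the closest pair of the series (Spearman 0.9971 across genes), and the labels do not say whether they came from separate animals. They were kept as separate libraries; summed into 1, 562 genes were called in Clpp KO against wild type in place of 249. Named genes and lists below whose call ended without replicates 2 and 4 are given in each comparison. That setting keeps wild-type replicates 1 and 3 alone, so its p-values may rest on 1 animal. It also turns the atrial imbalance. The atrial covariate was −0.174 and −0.196 log2 CPM in them, against 1.104 to 8.255 in Clpp KO and 4.745 to 8.265 in Fgf21 KO. A call lost or a list turned there does not by itself point to atrial tissue.

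**Figure D2:**
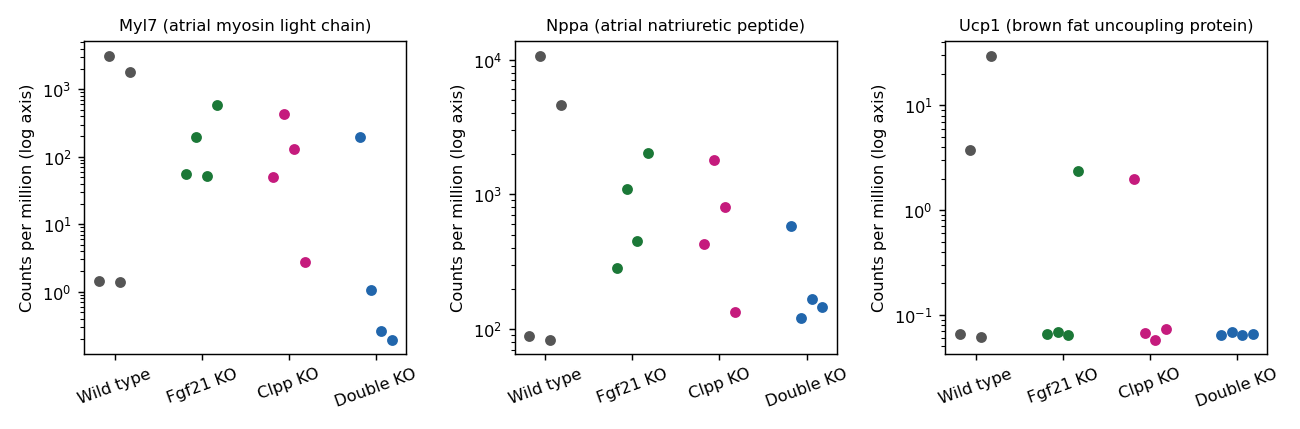
Myl7, Nppa and Ucp1 in each library on a log axis of CPM, with libraries under 3 counts drawn at the level of 3 counts. Wild-type replicates 2 and 4 lie at 3160 and 1800 CPM of Myl7, far above replicates 1 and 3.

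Loss of CLPP with Fgf21 intact was assessed in Clpp KO against wild type. Transcripts of 4 kinds were higher in the Clpp KO heart: interferon-stimulated genes, enzymes of serine, folate and asparagine synthesis, factors of the integrated stress response, and the mRNAs encoded in mitochondrial DNA. Usp18, a feedback inhibitor of interferon signalling, rose by 3.40 ± 0.17 on the log2 scale. Mthfd2, the mitochondrial folate enzyme, rose by 3.84 ± 0.42 (35.1 against 4.32 CPM), and Asns, asparagine synthetase, by 3.10 ± 0.32. Glutathione transferase Gsta2 rose by 4.31 ± 0.46. Clpp itself fell by 1.96 ± 0.16 (n = 4 each; edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 5.82e-06).

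Among 38 interferon-stimulated genes, which are induced by type I interferon, 24 rose and none fell in Clpp KO (34 rose when adjusted over the list alone), with a median log2 fold change of 1.02. Ifit1 rose by 2.62 ± 0.18, the transcription factor Irf7 by 2.18 ± 0.18 and Oasl1 by 2.31 ± 0.20. The list stood apart from all other genes in camera (adjusted p = 4.52e-74, and adjusted p = 0.00505 with an estimated correlation). Apol9a, outside the list, rose by 3.93 ± 0.52. Macrophage and monocyte markers had a median of 0.16 with 0 of 14 called, also over the list alone (camera adjusted p = 0.0506, and adjusted p = 0.659 with an estimated correlation), and of 0.70 without wild-type replicates 2 and 4 (camera adjusted p = 1.93e-10).

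The list of serine, one-carbon and proline synthesis had 7 of 19 members higher in Clpp KO (10 adjusted over the list alone; median 0.43). Phgdh, the first enzyme of serine synthesis, rose by 3.29 ± 0.46, and Aldh1l2, a mitochondrial folate dehydrogenase, by 2.67 ± 0.37. About 56.3% of the 31-mers of Phgdh also occur in other genes, mainly the pseudogene Gm7901, so its size is uncertain. The camera test of this list gave adjusted p = 2.07e-15, and adjusted p = 0.00178 with an estimated correlation. Factors of the integrated stress response had 4 of 22 members higher (9 adjusted over the list alone; median 0.25, and 0.51 without wild-type replicates 2 and 4; camera adjusted p = 9.97e-09, and adjusted p = 0.00505 with an estimated correlation). They were Atf5 at 2.07 ± 0.23, the pseudokinase Trib3 at 1.75 ± 0.25, Sesn2 at 1.11 ± 0.17 and the kinase Eif2ak2, which interferon also induces, at 1.02 ± 0.13.

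Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, rose in 10 of 20 cases (12 higher and 1 lower adjusted over the list alone; median 0.54), among them Iars at 0.95 ± 0.14, Gars at 0.74 ± 0.11, Sars at 0.77 ± 0.12 and Nars at 0.67 ± 0.10. For this list camera gave adjusted p = 3.94e-14, and adjusted p = 0.138 with an estimated correlation. Of 14 amino acid transporters only Slc7a5 was called, at 1.67 ± 0.23 (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00478, and adjusted p = 0.547 with an estimated correlation). Antioxidant and NRF2 targets had 5 of 29 members higher (10 higher and 3 lower adjusted over the list alone; camera adjusted p = 9.56e-05, and adjusted p = 0.446 with an estimated correlation). They included Gclm, a subunit of the first enzyme of glutathione synthesis, at 1.72 ± 0.36, Txnrd1 at 0.80 ± 0.16, Gsta4 at 0.78 ± 0.14 and Gsta1 at 3.15 ± 0.41. Gsta1 shares 92.9% and Gsta2 60.7% of 31-mers with other genes, chiefly of their own family.

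Of 13 mRNAs encoded in mitochondrial DNA, which specify subunits of the respiratory chain and ATP synthase, 11 rose (12 adjusted over the list alone; median 1.54; camera adjusted p = 0.0223 with an estimated correlation). Among them were mt-Co2 at 1.38 ± 0.18, mt-Atp6 at 1.65 ± 0.23 and mt-Nd1 at 1.71 ± 0.24. Of the 31-mers of mt-Co2 99.5% occur in the nuclear copy Gm28661 and of those of mt-Atp6 99.5% in Gm10925, while mt-Nd1 shares 0%. The 13 mRNAs made up 58.0 ± 1.44% of all counts in Clpp KO and 33.2 ± 7.09% in wild type, a difference of 24.8 points (SD, n = 4 each, exact two-sided permutation test p = 0.0286, adjusted p over 5 comparisons = 0.0476). With a library left out the smallest possible p is 0.0571. The wild-type share was 39.1% and 39.4% in replicates 1 and 3, and 25.5% and 28.9% in replicates 2 and 4. The difference is therefore smaller against replicates 1 and 3 alone. Nuclear subunits of complex I had 0 of 37 members called and a median of −0.21 (camera adjusted p = 0.000154, and adjusted p = 0.659 with an estimated correlation). Mitochondrial chaperones and proteases had 0 of 23 members called and a median of 0.22 (camera adjusted p = 0.000315, and adjusted p = 0.656 with an estimated correlation), and without wild-type replicates 2 and 4 their direction turned (adjusted p = 0.89). Fatty acid oxidation genes had 0 of 36 members called (median 0.34, and 0.05 without those replicates; camera adjusted p = 0.0001, 0.656 with an estimated correlation, and 0.197 without those replicates).

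Genes lower in Clpp KO included Edn3 (endothelin 3, −1.99 ± 0.47), Dct (a melanin synthesis enzyme, −1.66 ± 0.24), Stmn2 (a neuronal tubulin-binding protein, −1.53 ± 0.28), Gfra2 (a neurturin receptor, −1.42 ± 0.34) and Alas1 (the first enzyme of haem synthesis, −1.34 ± 0.32). Markers of Schwann cells, the conduction system and adipocytes had medians of −0.81, −1.11 and −3.34 with none called (4, 1 and 0 lower adjusted over the list alone; camera adjusted p = 0.00289, 0.0351 and 0.00572, and adjusted p = 0.649, 0.656 and 0.656 with an estimated correlation). Without wild-type replicates 2 and 4 these medians were −0.01, 1.07 and 1.84 (camera adjusted p = 0.761, 0.518 and 0.518). Neutrophil markers fell in 2 of 4 cases, S100a8 by 2.78 ± 0.51 and S100a9 by 2.60 ± 0.62 (4 adjusted over the list alone; camera adjusted p = 0.000154, and adjusted p = 0.138 with an estimated correlation), with a wild-type mean of 0.847 CPM for S100a8. Red blood cell markers had a median of −1.66 with 0 of 8 called, also over the list alone (camera adjusted p = 0.000387, and adjusted p = 0.649 with an estimated correlation). Of 12 endothelial markers, Pecam1 fell by 0.56 ± 0.12 (6 lower adjusted over the list alone; camera adjusted p = 0.000315, and adjusted p = 0.347 with an estimated correlation). Atrial cardiomyocyte markers had a median of −0.72 with 0 of 12 called, and 4.19 without wild-type replicates 2 and 4. Matrix and fibrosis genes had a median of −0.43 with 0 of 31 called, and 0.13 without those replicates (camera adjusted p = 0.000154 with them, 0.656 with an estimated correlation and 0.982 without them). Of FGF receptors and ERK feedback genes, Dusp4 at 2.15 ± 0.44 and Etv5 at 0.88 ± 0.19 rose among 20 (2 higher adjusted over the list alone; median −0.05 and mean −0.03, while camera pointed up at adjusted p = 0.552). Etv5 shares 30.3% of its 31-mers with the pseudogene Gm4798. Without wild-type replicates 2 and 4 the median of this list was 0.08. These genes were then no longer called: Edn3 at −1.51 (adjusted p = 0.112), Stmn2 at −0.95 (0.0904), Gfra2 at −0.77 (0.401), S100a8 at −2.20 (0.102), S100a9 at −1.87 (0.298), Pecam1 at −0.43 (0.109), Dusp4 at 2.02 (0.171), Etv5 at 0.81 (0.144) and Gclm at 1.67 (0.2).

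In all, edgeR with Benjamini-Hochberg called 249 of 15255 genes in Clpp KO against wild type, 165 higher and 84 lower. DESeq2 called 847 (445 higher, 402 lower) and limma voom with quality weights 2815 (1403 and 1412). Without wild-type replicates 2 and 4, 159 were called, 132 higher and 27 lower. Leaving out single libraries gave 504, 949 and 138 without wild-type replicates 1, 3 and 4, and 114, 134, 125 and 124 without Clpp KO replicates 1 to 4. Calls were also near balance without wild-type replicate 1 (235 higher, 269 lower) or 3 (454 and 495). So they were with both summed (266 and 296) and with the atrial covariate (516 and 523). In the other settings, apart from library size alone, most calls were higher. Scaled by library size alone, in which the larger mtDNA share lowers every other gene, the median of all genes shifted to −0.79 and 0.8% of 11933 calls were higher. The medians of the stress response, serine, synthetase, transporter and NRF2 lists then lay at −0.47, −0.29, −0.16, −0.48 and −0.51, below 0 but above that shift, as did chaperones at −0.48 and fatty acid oxidation at −0.39, and those of the interferon and mtDNA lists at 0.24 and 0.86.

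Loss of FGF21 alone was assessed in Fgf21 KO against wild type. Few genes differed, and those with a symbol of their own were neighbours of Fgf21 on chromosome 7. Kcnj14, a potassium channel gene 203 kb from Fgf21, was 46.5 ± 13.6 CPM in Fgf21 KO and 0.514 ± 0.328 in wild type (SD, n = 4 each), a log2 rise of 6.57 ± 0.43. Ush1c, a scaffold gene 581 kb away, rose by 2.49 ± 0.28 and Bcat2, the mitochondrial branched-chain aminotransferase 44 kb away, by 1.34 ± 0.20. Mamstr, a muscle transcription coactivator 26 kb away, fell by 1.27 ± 0.18 (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.00767, and 2.41e-06, 0.000688 and 0.0127 for Kcnj14, Ush1c and Bcat2). Clpp was not called (0.16 ± 0.15, adjusted p = 0.679), and Mamstr was not without wild-type replicates 2 and 4 (−0.99, adjusted p = 0.0616).

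edgeR called 7 genes in this comparison, 5 higher and 2 lower. The other 3, named after their values were seen, were Gm14659 on chromosome X (4.06 ± 0.40), Gm5522 on chromosome 1 and Ftl1-ps1 on chromosome 13 (−4.34 ± 0.48). Gm5522 had 0 counts in all wild-type libraries and 63 in Fgf21 KO, at least 22.8-fold higher by TMM with a floor of 3 counts over the group. It was not called without Fgf21 KO replicate 1 (adjusted p = 0.0609) or without wild-type replicates 2 and 4 (0.0878). Of the 31-mers of Gm5522, 78.8% occur in Kcnj14, and of those of Ftl1-ps1, 63.5% occur in Ftl1, which also lies on chromosome 7. DESeq2 called 34 genes and limma voom 111. Scaled by library size alone, 60% of 10 calls were higher against 71.4%, the median of all genes was −0.23, and that of nuclear complex I subunits was −0.01 in place of 0.20.

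No member of the serine list or of the stress response list was called in Fgf21 KO against wild type (camera adjusted p = 0.287 and 0.876). Interferon-stimulated genes had 0 of 38 members called, 16 lower when adjusted over the list alone, a median of −0.40 and camera adjusted p = 3.69e-15, with adjusted p = 0.401 with an estimated correlation. Without wild-type replicates 2 and 4 that median was −0.22 (camera adjusted p = 2.22e-05). Fatty acid oxidation genes had a median of 0.47 and 0 called (camera adjusted p = 7.86e-12, and adjusted p = 0.401 with an estimated correlation), and of 0.19 without those replicates (0.000986). Matrix genes had a median of −0.54 and 0 called (3.09e-09, and adjusted p = 0.401 with an estimated correlation), which was 0.02 without those replicates (0.786). Fibroblast, atrial and ventricular markers had medians of −0.57, −1.02 and 0.29 with none called, also over the lists alone (camera adjusted p = 6.62e-06, 0.369 and 0.00438, and adjusted p = 0.401, 0.834 and 0.401 with an estimated correlation). Without those replicates they were 0.02, 3.92 and −0.07 (camera adjusted p = 0.51, 4.42e-07 and 0.567). FGF receptors and ERK feedback genes had a median of −0.26 with 0 of 20 called, 2 lower adjusted over the list alone (camera adjusted p = 0.00279, adjusted p = 0.401 with an estimated correlation, and 0.0578 without those replicates). Of 47 lists 32 passed in this comparison, 17 without wild-type replicates 2 and 4, and 0 with an estimated correlation or with fry. The mtDNA share was 36.1 ± 4.62% against 33.2 ± 7.09% (SD, n = 4 each, exact permutation test p = 0.686).

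**Figure D3:**
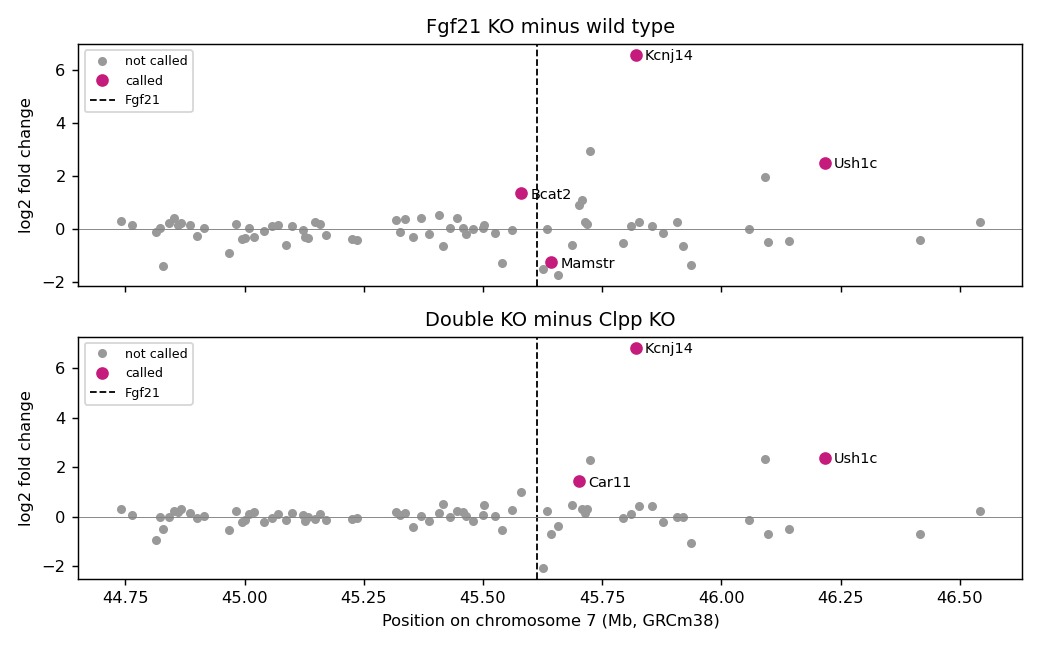
Log2 fold changes of tested genes within 1 Mb of Fgf21 (dashed line) against position on chromosome 7 (Mb, GRCm38), for Fgf21 KO against wild type and double KO against Clpp KO; coloured points are called genes. Kcnj14 lies at 6.57 and Ush1c at 2.49 in Fgf21 KO against wild type.

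Whether FGF21 alters the response to loss of CLPP was assessed in double KO against Clpp KO. Vmn2r3, annotated as a vomeronasal receptor, was the only gene with a symbol of its own called lower, by 2.08 ± 0.28, and it had been among the genes most raised in Clpp KO against wild type (3.70 ± 0.30). Its level was 0.468 ± 0.241 CPM in wild type, 3.48 ± 0.639 in Clpp KO and 0.758 ± 0.319 in double KO (SD, n = 4 each). Near Fgf21, Kcnj14 rose by 6.83 ± 0.46, Ush1c by 2.40 ± 0.28 and Car11, a carbonic anhydrase-related gene 86 kb away, by 1.43 ± 0.23. mt-Nd3, a complex I subunit, rose by 1.44 ± 0.20 (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.00529), while the median of the other 12 mtDNA-encoded mRNAs was 0.14. The sum of mt-Nd3 and its nuclear copy Gm28438, which share reads, was at 0.57 ± 0.21 and was not called (adjusted p = 0.994 by edgeR).

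Enzymes of serine, one-carbon and proline synthesis stood lower as a list in double KO than in Clpp KO. None of the 19 was called over all genes, 7 were lower when adjusted over the list alone, the median was −0.09 and the mean −0.45. camera gave adjusted p = 1.82e-09, and adjusted p = 0.00881 with an estimated correlation. Asns was at −1.42 ± 0.30 and Pycr1, of proline synthesis, at −1.18 ± 0.28 (adjusted p = 0.234 and 0.437 by edgeR, and 0.0172 for Asns without wild-type replicates 2 and 4). Mthfd2, chosen after its values were seen, was 35.1 ± 6.07 CPM in Clpp KO and 11.8 ± 6.26 in double KO (SD, n = 4 each). The mean log2 CPM of the list was 2.13 ± 0.20 in wild type, 1.97 ± 0.08 in Fgf21 KO, 3.24 ± 0.04 in Clpp KO and 2.73 ± 0.23 in double KO, so double KO lay between Clpp KO and wild type. The Clpp KO libraries stand in both comparisons, so a chance deviation in them would appear as a rise in one and a fall in the other.

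The stress response list had 0 of 22 members called and a median of −0.18, with 1 lower adjusted over the list alone (camera adjusted p = 2.37e-05, and adjusted p = 0.0422 with an estimated correlation). Atf5 was at −0.92 ± 0.22 and Sesn2 at −0.50 ± 0.17 (adjusted p = 0.437 and 0.994 by edgeR). Aminoacyl-tRNA synthetases had a median of −0.14 with 0 of 20 called, also over the list alone (camera adjusted p = 0.00384, and adjusted p = 0.822 with an estimated correlation). Interferon-stimulated genes did not stand apart, with a median of −0.02, a mean of 0.00 and 0 of 38 called, also over the list alone (camera pointed up at adjusted p = 0.969, and at 0.0116 without Clpp KO replicate 1). The list scores of this group were 3.64 ± 0.20 in Clpp KO and 3.64 ± 0.23 in double KO. Nuclear subunits of complex I had a median of 0.25 with 0 of 37 called, also over the list alone (camera adjusted p = 1.37e-13, and adjusted p = 0.811 with an estimated correlation). FGF receptors and ERK feedback genes had a median of −0.13 with 0 of 20 called, also over the list alone (camera adjusted p = 0.0308, adjusted p = 0.782 with an estimated correlation, and 0.0628 without wild-type replicates 2 and 4). Atrial markers moved with these groups, with a median of −1.45 and 0 of 12 called (camera adjusted p = 0.000132, and adjusted p = 0.811 with an estimated correlation).

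edgeR called 9 genes in double KO against Clpp KO, 6 higher and 3 lower, of 542 at an unadjusted p under 0.05. DESeq2 called 35 and limma voom 41, and without wild-type replicates 2 and 4 edgeR called 15. Leaving out single libraries gave 6 to 10. Scaled by library size alone, 55.6% of 9 calls were higher against 66.7%, the median of all genes was −0.14, and that of mtDNA-encoded mRNAs was −0.01 in place of 0.15. Of 47 lists 20 passed, 2 with an estimated correlation, 11 without Clpp KO replicate 2 and 13 without double KO replicate 3. The 4 called genes without a symbol of their own, named after their values were seen, were Gm14659 (4.40 ± 0.43), Gm5522, Ftl1-ps1 (−6.18 ± 0.63, with 363 counts in Clpp KO and 4 in double KO) and Glns-ps1. Gm5522 had 0 counts in all Clpp KO libraries and 53 in double KO, at least 20.3-fold higher by TMM with a floor of 3 counts over the group. It was not called without Clpp KO replicate 1 (adjusted p = 0.0513) or double KO replicates 1 or 4 (0.0558 and 0.0586). Glns-ps1 had 211, 236, 1 and 119 counts in Clpp KO replicates 1 to 4 and 2 over double KO, a ratio of 247 by TMM (95% counting interval 68.1 to 2040). It shares 46.9% of its 31-mers with Glul. It was called at adjusted p = 0.0486, at 3.57e-05 without Clpp KO replicate 3, and not without Clpp KO replicates 1, 2 or 4 (0.135, 0.114 and 0.104), any 1 double KO library (0.193 to 0.312) or wild-type replicates 2 and 4 (0.0758). In Fgf21 KO against wild type Glns-ps1 was not called (unadjusted p = 3.55e-05 by edgeR). It had 153, 56, 139 and 84 counts in wild-type replicates 1 to 4 and 0, 1, 0 and 0 in Fgf21 KO. Clpp was at −0.05 ± 0.16 (adjusted p = 0.994), and the mtDNA share at 58.8 ± 1.99% against 58.0 ± 1.44% (SD, n = 4 each, exact permutation test p = 0.543).

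**Figure D4:**
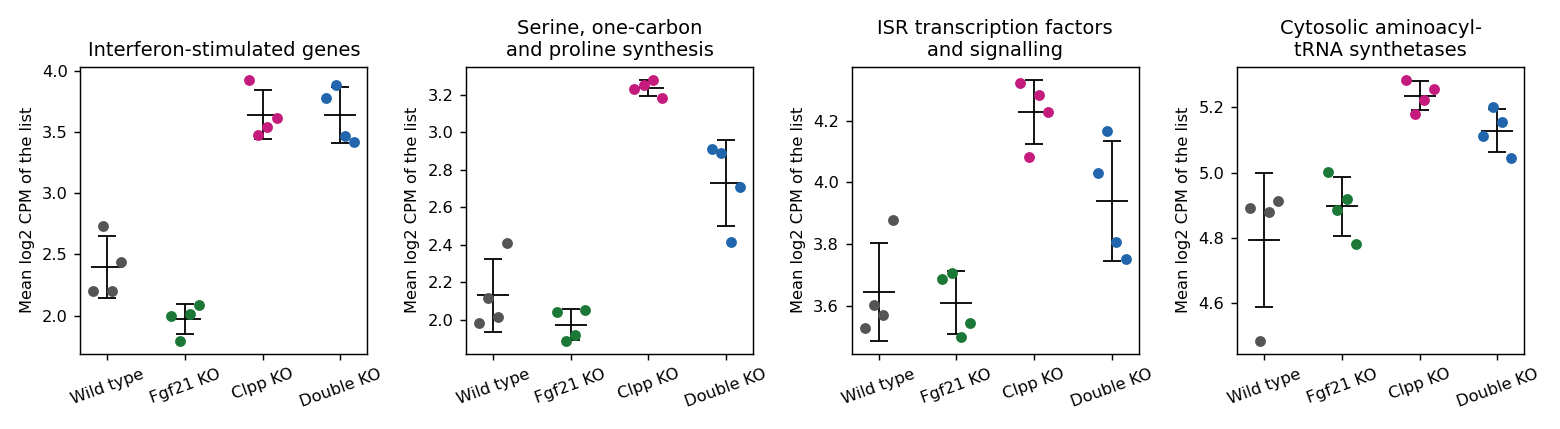
Mean log2 CPM of 4 gene lists in each library (dots), with group means and SD as bars. The serine list averages 2.13 in wild type, 3.24 in Clpp KO and 2.73 in double KO, and the interferon list 3.64 in both groups lacking Clpp.

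Loss of CLPP in mice without Fgf21 was assessed in double KO against Fgf21 KO, which shares no library with Clpp KO against wild type. The same kinds of transcript rose. Among interferon-stimulated genes 35 of 38 rose (37 adjusted over the list alone; mean log2 fold change 1.69; adjusted p = 5.63e-05 with an estimated correlation), including Usp18 by 3.94 ± 0.17, Ifit1 by 3.04 ± 0.19, Irf7 by 2.83 ± 0.19 and the nucleic acid sensor Zbp1 by 2.94 ± 0.36. Apol9a rose by 5.30 ± 0.57 and Gsta2 by 3.98 ± 0.45. The chemokine Ccl5 rose by 1.59 ± 0.36. Macrophage and monocyte markers had a median of 0.31 with 0 of 14 called, and 3 higher adjusted over the list alone (camera adjusted p = 0.000159, and adjusted p = 0.614 with an estimated correlation). Clpp fell by 2.18 ± 0.16 (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 9.65e-07).

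Of the 19 serine and folate enzymes 4 rose in double KO against Fgf21 KO (7 adjusted over the list alone; median 0.41; adjusted p = 0.00232 with an estimated correlation): Mthfd2 by 3.31 ± 0.42, Phgdh by 2.48 ± 0.47, Asns by 2.34 ± 0.32 and Psat1 by 1.04 ± 0.22. Of the stress response list Atf5 rose by 1.26 ± 0.22 and Eif2ak2 by 0.97 ± 0.13 (2 of 22, and 5 adjusted over the list alone; median 0.17; adjusted p = 0.0303 with an estimated correlation). The transporter Slc7a5 rose by 1.37 ± 0.23 (1 of 14, also over the list alone; camera adjusted p = 0.0142, and adjusted p = 0.614 with an estimated correlation). No synthetase was called, 7 of 20 were higher adjusted over the list alone, and the median was 0.25 (camera adjusted p = 5.93e-07, and adjusted p = 0.614 with an estimated correlation). mtDNA-encoded mRNAs rose in 10 of 13 cases (13 adjusted over the list alone; median 1.47; adjusted p = 0.00632 with an estimated correlation), among them mt-Co2 by 1.47 ± 0.18, mt-Atp6 by 1.56 ± 0.22 and mt-Nd1 by 1.43 ± 0.23. Their share of counts was 58.8 ± 1.99% against 36.1 ± 4.62% (SD, n = 4 each, exact permutation test p = 0.0286, adjusted p over 5 comparisons = 0.0476). Nuclear complex I subunits had a median of −0.18 with 0 of 37 called, also over the list alone (camera adjusted p = 5.12e-05, and adjusted p = 0.824 with an estimated correlation). Ano10, a scramblase family member, fell by 0.88 ± 0.19, the sugar phosphate carrier Slc37a2 by 0.84 ± 0.14 and the kinase subunit Camk2b by 0.64 ± 0.13. Atrial markers had a median of −1.21 with 0 of 12 called (camera adjusted p = 0.00126, and adjusted p = 0.731 with an estimated correlation).

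edgeR called 136 genes in double KO against Fgf21 KO, 126 higher and 10 lower. DESeq2 called 209, limma voom 370, and edgeR 241 without wild-type replicates 2 and 4, where 15540 genes passed the filter. Scaled by library size alone, 0.9% of 10858 calls were higher, the median of all genes was −0.70, and the medians of the serine, stress response, synthetase and transporter lists were −0.27, −0.53, −0.44 and −0.46, above that shift.

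Of the 165 genes called higher in Clpp KO against wild type and the 126 in double KO against Fgf21 KO, 88 were shared, where independent lists would share 1.36 (Fisher exact test p = 7.02e-154). Of the 84 and 10 called lower, 5 were shared, where independent lists would share 0.0551 (Fisher exact test p = 1.11e-09). These tests treat genes as independent, and both comparisons come from 1 model, so the p-values do not measure the spread between libraries. Across the 15255 genes, which are not independent replicates, the fold changes of both comparisons had a Pearson correlation of 0.576 (jackknife SE over libraries 0.112) and a Spearman correlation of 0.610. Across the 292 genes called in either comparison, chosen by these same effects, which favours a high value, the Pearson correlation was 0.867. Over all genes it was 0.264 without wild-type replicates 2 and 4.

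**Figure D5:**
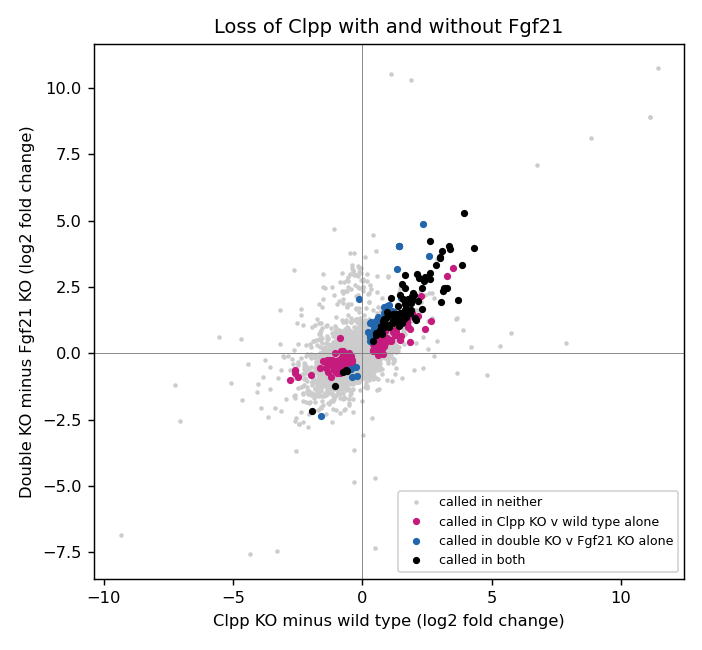
Log2 fold changes of Clpp KO against wild type (x) and of double KO against Fgf21 KO (y) for 15255 genes, coloured by the comparison that called them. Genes called in both lie near the diagonal. Pearson's correlation is 0.576 over all genes and 0.867 over the 292 called in either, which were chosen by these same effects.

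The joint loss was assessed in double KO against wild type. Interferon-stimulated genes rose in 25 of 38 cases (35 adjusted over the list alone; median 1.11; adjusted p = 0.0149 with an estimated correlation), with Usp18 at 3.24 ± 0.17, Ifit1 at 2.55 ± 0.18 and Irf7 at 2.30 ± 0.18. mtDNA-encoded mRNAs rose in 11 of 13 cases (13 adjusted over the list alone, median 1.74, adjusted p = 0.0156 with an estimated correlation), and mt-Nd3 by 2.83 ± 0.21. Summed with its nuclear copy Gm28438, with which it shares reads, mt-Nd3 was at 2.202 ± 0.215. Of the serine list Mthfd2 rose by 2.39 ± 0.40 and Asns by 1.68 ± 0.31 (2 of 19, and 9 adjusted over the list alone; median 0.51, and 0.25 without wild-type replicates 2 and 4; camera adjusted p = 8.06e-06, and adjusted p = 0.0527 with an estimated correlation). Of the stress response list Atf5 at 1.15 ± 0.22, Trib3 at 1.10 ± 0.25 and Eif2ak2 at 0.84 ± 0.13 rose (3 of 22, 5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00254, and adjusted p = 0.197 with an estimated correlation). NRF2 targets had 7 of 29 members higher (14 higher and 3 lower adjusted over the list alone; camera adjusted p = 2.66e-08, and adjusted p = 0.213 with an estimated correlation), including Gclm at 1.91 ± 0.36 and Txnrd1 at 0.84 ± 0.16. Sqstm1, an autophagy receptor, rose by 1.38 ± 0.26 and Acta1, skeletal α-actin, which is also expressed in the fetal and stressed heart, by 1.68 ± 0.37. Kcnj14 rose by 6.29 ± 0.43 and Bcat2 by 1.11 ± 0.20. Aldh1a3, a retinaldehyde dehydrogenase, fell by 2.21 ± 0.53 and Edn3 by 2.01 ± 0.48. Clpp fell by 2.02 ± 0.16 (edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 2.4e-06). Atrial markers had a median of −2.24 with 0 of 12 called (camera adjusted p = 0.00492, and adjusted p = 0.597 with an estimated correlation), and fibroblast markers of −0.88 with 0 of 12 called and 9 lower adjusted over the list alone (2.95e-06, and adjusted p = 0.417 with an estimated correlation). Without wild-type replicates 2 and 4 these medians were 2.71 and −0.17 (camera adjusted p = 0.102 and 0.0836). Schwann cell, conduction system and adipocyte markers had medians of −1.02, −1.54 and −4.34 with none called (7, 1 and 7 lower adjusted over the list alone; camera adjusted p = 0.000217, 0.0183 and 0.00446, and adjusted p = 0.417, 0.561 and 0.446 with an estimated correlation). Without those replicates they were −0.24, 0.88 and 0.62 (camera adjusted p = 0.219, 0.69 and 0.902). These genes were then no longer called: Aldh1a3 at −0.77 (adjusted p = 0.468), Edn3 at −1.55 (0.119), Trib3 at 1.29 (0.0934), Acta1 at 1.84 (0.0909), Gclm at 1.85 (0.174) and Sqstm1 at 1.32 (0.129). The synthetases Nars at 0.36 (adjusted p = 0.066 by edgeR) and Iars at 0.359 (0.224) also lost their call.

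edgeR called 233 genes in double KO against wild type, 160 higher and 73 lower. DESeq2 called 959, limma voom 964 and edgeR 148 without wild-type replicates 2 and 4. Leaving out single libraries gave 870, 1116 and 146 without wild-type replicates 1, 3 and 4, and 141, 129, 144 and 150 without double KO replicates 1 to 4. Most calls were lower in DESeq2 (409 higher, 550 lower) and with wild-type replicates 1 and 3 summed (288 and 533). The same held without wild-type replicate 1 (294 and 576) or 3 (413 and 703). In the other settings, apart from library size alone, most calls were higher. Scaled by library size alone, 0.6% of 13124 calls were higher and the median of all genes was −0.92; the medians of the serine, stress response and NRF2 lists were then −0.39, −0.49 and −0.50, above that shift.

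The interaction tested whether the effect of Fgf21 loss differed between mice with and without CLPP. edgeR called 0 of 15255 genes, with 299 at an unadjusted p under 0.05, while DESeq2 called 3 and limma voom 1. The smallest p-values belonged to Eps8l1, an actin regulator (1.44 ± 0.30), Nab1, a corepressor of EGR factors (0.83 ± 0.18), Vmn2r3 (−1.71 ± 0.42), Vps33b, of vesicle sorting (0.89 ± 0.24), and Gm17538, all at adjusted p = 1. Aldh1l2 was at −1.46 ± 0.50 and Atf5 at −0.81 ± 0.31 (adjusted p = 1 each). The serine list had a median of −0.33 and the stress response list of −0.13, with no member called, also over the list alone (camera adjusted p = 0.000162 and 0.000577, and adjusted p = 0.188 for each with an estimated correlation). Interferon-stimulated genes had a median of 0.40 (camera adjusted p = 1.34e-17, and adjusted p = 0.274 with an estimated correlation) and synthetases of −0.20 (6.25e-07, and adjusted p = 0.501 with an estimated correlation). Of 47 lists 22 passed, and 0 did with an estimated correlation or with fry. Without wild-type replicates 2 and 4 the medians of the serine and interferon lists were −0.10 and 0.21. In simulation this contrast recovered 0% of 1.5-fold, 35.8% of 2-fold and 71.2% of 4-fold changes.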

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

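The tests on the genes called between Fgf21 genotypes, the sum of mt-Nd3 and Gm28438, the atrial covariate, the genes lower in Clpp KO without wild-type replicates 2 and 4, and the splits for counts of lists and for named lists were chosen after those results were seen. The other tests of this part were planned.

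The first pattern is the position of the genes called between Fgf21 genotypes. Of the 11 genes called in Fgf21 KO against wild type or in double KO against Clpp KO, 5 lie within 20 Mb of Fgf21, against 352 of the 15255 tested (Fisher exact test p = 2.62e-06, which treats genes as independent), and these 5 lie within 581 kb. Atrial tissue in the wild-type libraries was checked in double KO against Clpp KO, which holds no wild-type library. There 7 of the 7 genes called in Fgf21 KO against wild type had the same sign with an unadjusted p under 0.05. Mean Myl7 was lower in the group lacking Fgf21 in both comparisons, at 222 against 1240 CPM and at 49.5 against 154 CPM. The same sign therefore does not tell atrial tissue from another source. Without wild-type replicates 2 and 4, 5 of the 7 were still called, so these do not rest on those replicates. The positions of the genes near Fgf21 are those that a chromosome segment carried along with the targeted allele, or an effect of that allele on its neighbours, could give. These cannot be separated without genotypes. An action of FGF21 on genes elsewhere stays open, since 1 gene called in both comparisons, Gm14659, lies outside the region with under 10% of 31-mers shared with it. Glns-ps1 on chromosome 11, called in double KO against Clpp KO alone, was also lower in Fgf21 KO than in wild type (−8.01, unadjusted p = 3.55e-05 by edgeR).

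The second pattern is the higher mt-Nd3 in both groups lacking Fgf21. A general rise of mtDNA-encoded mRNAs is argued against, with a median of 0.14 for the other 12 in double KO against Clpp KO, where mt-Nd3 was at 1.44. Gm28438, a nuclear copy holding 98.1% of the 31-mers of mt-Nd3, had 1340 ± 261 CPM in wild type, 16.7 ± 24.7 in Fgf21 KO, 3310 ± 439 in Clpp KO and 7.40 ± 5.97 in double KO (SD, n = 4 each). The sum of mt-Nd3 and Gm28438 differed by 0.57, under 0.5 times the value of mt-Nd3 alone, so a different assignment of shared reads could account for most of the rise. The remaining 0.57 ± 0.21 did not pass over all genes (adjusted p = 0.994 by edgeR) and was not tested alone, so it stays open.

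The third pattern is the 84 genes called lower in Clpp KO than in wild type, with a median of −0.82. Without wild-type replicate 2, which had few Y-linked counts, their median was −0.72, and 27 of the 84 were then called. Without wild-type replicates 2 and 4 the median was −0.59 (quartiles −0.78 and −0.47). All 84 then stayed below 0, with 12 called from fewer libraries. Both medians were over 0.5 times the first value. The genes had been chosen with the remaining wild-type and Clpp KO libraries as well, which favours values below 0. These medians therefore cannot decide whether sex or atrial tissue was the whole source. With the atrial covariate the median was −0.82. That covariate was −0.174, 10.074, −0.196 and 9.45 log2 CPM in wild-type replicates 1 to 4. In Clpp KO replicates 1 to 4 it was 5.356, 8.255, 6.754 and 1.104. Its group means were thus close, so it could hardly move the fold changes of this contrast, although 1039 genes were called with it. In double KO against Fgf21 KO, which holds no wild-type library, their median was −0.38, just under 0.5 times the first value. The atrial covariate differed between those groups, at 4.745 to 8.265 log2 CPM in Fgf21 KO. In double KO replicates 1 to 4 it was 7.295, −0.015, −1.596 and −1.973. A fall in that comparison therefore does not tell atrial tissue from loss of CLPP, and a part from atrial tissue stays open. Loss of CLPP stays open too, with 54.8% of them lower at an unadjusted p under 0.05 there, where the 165 genes called higher had a median of 1.195 against 1.29.

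Other assignments of the same libraries to groups were tested next. For Clpp KO against wild type 1 of 35 splits, the real one with 249 genes, called as many, and the highest other called 0. The real split also called the most in double KO against Clpp KO (1 of 35, 9 genes against 1), double KO against Fgf21 KO (1 of 35, 136 against 1) and double KO against wild type (1 of 35, 233 against 5). For each, 1 of 35 is the smallest share there can be, and wild-type replicates 1 and 3 may not be separate animals. Chance is thus made less likely by these splits and is not excluded. For Fgf21 KO against wild type 3 of 35 splits called as many as the real 7, the highest 1023 and the next 573. In both of these, wild-type replicates 2 and 4 stood apart from replicates 1 and 3, which points to a structure of the samples. For the interaction 100 of 100 splits drawn called as many as the real 0, which a count of 0 makes certain, so this test decides nothing. The highest called 240. These splits drew all libraries over all groups, so they also mixed the effects of Clpp loss and do not test the interaction by itself.

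Counts of lists did not exclude chance. As many lists passed in 14 of 35 splits of Clpp KO against wild type (28 real, 33 highest other), 5 of 35 of Fgf21 KO against wild type (32 and 35), and 10 of 35 of double KO against Clpp KO (20 and 33). The same counts were 8 of 35 for double KO against Fgf21 KO (19 and 25), 6 of 35 for double KO against wild type (30 and 33) and 53 of 100 for the interaction (22 and 37). For single lists 1 of 35 is the smallest share there can be, and these lists were singled out of 47 after their results were seen, so the splits do not exclude chance for them. The serine list had its smallest camera p in the real split for Clpp KO against wild type (other smallest p 1.76e-09), double KO against Clpp KO (3.49e-05) and double KO against Fgf21 KO (3.83e-10), 1 of 35 each. The stress response list did so in Clpp KO against wild type (1 of 35; 2.48e-09) and in double KO against Fgf21 KO (1 of 35; 4.83e-06), but not in double KO against Clpp KO (2 of 35; 4.81e-09). Interferon-stimulated genes did so in Clpp KO against wild type (1 of 35; 4.04e-52) and in double KO against Fgf21 KO (1 of 35; 1.46e-56), and not in double KO against Clpp KO (35 of 35; 1.35e-37).

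Single libraries stood far from the other 3 of their group in 20 of 344 groups of values, where chance gives about 1 in 20, or 17.2. Levels of genes and lists here are log2 CPM scaled by TMM. Of these 4 were in wild-type replicate 2, 4 in Fgf21 KO replicate 2, and 3 each in Fgf21 KO replicate 1 and Clpp KO replicate 1. In Fgf21 KO replicate 1 the mtDNA share was 29.15% (nearest other 37.78%), Ano10 was at 5.727 log2 CPM (5.167) and mt-Co2 at 15.196 (15.045). In Fgf21 KO replicate 2 Asns was at 0.062 (0.731), Gclm at 4.724 (3.228), Phgdh at −0.959 (−0.09) and the list of the endoplasmic reticulum unfolded protein response at 4.925 (5.351). In Fgf21 KO replicate 4 Slc37a2 was at 1.827 (1.679). In wild-type replicate 2 Sec14l5 was at 3.858 (1.634), Vmn2r3 at −1.01 (−1.597), the synthetase list at 4.484 (4.88) and fatty acid oxidation at 6.254 (6.843), and in replicate 4 NRF2 targets were at 5.681 (5.033). In Clpp KO replicate 1 Eif2ak2 was at 3.741 (3.323), Gsta1 at 3.512 (3.037) and Ifit1 at 4.759 (4.211). Asns was at 4.56 (4.264) in Clpp KO replicate 2, Kcnj14 at −2.399 (−1.515) in replicate 3 and Sec14l5 at 0.069 (0.937) in replicate 4, and fatty acid oxidation at 7.609 (7.127) in double KO replicate 3.

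In the interaction test of camera 22 lists passed, 4 of them named here. As many passed in 53 of 100 splits, but those splits mixed all genotypes and cannot decide whether the interaction exceeds chance. None of these lists passed with an estimated correlation. A different effect of Fgf21 loss with and without CLPP was thus not shown for these lists. Their medians were 0.40 for interferon-stimulated genes, −0.33 for the serine list, −0.13 for the stress response list and −0.20 for synthetases, and with an estimated correlation no list passed (lowest adjusted p = 0.188).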

How the results depend on the processing

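Leaving out wild-type replicates 2 and 4, summing wild-type replicates 1 and 3, the atrial covariate, 1 entry per symbol and the leave-one-out list tests were chosen after the data were seen. Of 3204 alternative values for named genes 2886 kept direction and side of the threshold, 302 fell short of it in the same direction, 9 passed it and 7 changed sign. Of 865 for named lists the numbers were 742, 89, 15 and 19. Causes were not tested except where fewer libraries or the scaling itself give them.

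Scaled by library size only, 11933 genes were called in Clpp KO against wild type, 10858 in double KO against Fgf21 KO and 13124 in double KO against wild type. Nars then lay at −0.056 in Clpp KO against wild type, and Txnrd1, Nars and Iars at −0.021, −0.39 and −0.253 in double KO against wild type. Clpp, not called, lay at −0.043 in Fgf21 KO against wild type, and ranged from −0.115 to 0.009 in double KO against Clpp KO without single libraries, turning without Clpp KO replicate 4 and double KO replicate 1.

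For Clpp KO against wild type the counts were 115 with a fold minimum of 1.2, 847 in DESeq2 (52.5% higher), 2815 in voom, 151 in a fit to both groups alone, 562 with wild-type replicates 1 and 3 summed, 159 without replicates 2 and 4, 1039 with the atrial covariate and 93 at 0.01. Single libraries left out gave 114 to 949. For double KO against wild type they were 118, 959 (42.6% higher), 964, 56, 821, 148, 149 and 77, with 148 for sex as a covariate and 129 to 1116 without single libraries. For double KO against Fgf21 KO they were 209 in DESeq2, 370 in voom, 241 without wild-type replicates 2 and 4 and 90 at 0.01, and 94 to 127 without single libraries. For Fgf21 KO against wild type they were 34 in DESeq2, 111 in voom and 34 with the atrial covariate, and 5 to 8 without single libraries. For double KO against Clpp KO they were 35, 41 and, without wild-type replicates 2 and 4, 15, and 6 to 10 without single libraries. The interaction gave 3 in DESeq2, 1 in voom and 2 with the atrial covariate.

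With the repeat number as a replicate block 146 genes were called in Clpp KO against wild type, 8 in Fgf21 KO against wild type, 6 in double KO against Clpp KO, 109 in double KO against Fgf21 KO, 164 in double KO against wild type and 0 in the interaction. Libraries with the same number did not deviate together: 4 of 24 such pairs correlated over 0.1 (median −0.009), and the own number correlated best in 11 of 48 cases, so the numbers were not taken as paired.

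Lists past the threshold with an estimated correlation and with fry were 4 and 8 in Clpp KO against wild type, 0 and 0 in Fgf21 KO against wild type, 2 and 1 in double KO against Clpp KO, 4 and 4 in double KO against Fgf21 KO, 2 and 8 in double KO against wild type and 0 and 0 in the interaction. Fgf21 KO against wild type had 17 without wild-type replicates 2 and 4, and double KO against Clpp KO 11 to 27 without single libraries. The correlation of the effects of Clpp loss was 0.264 without wild-type replicates 2 and 4, 0.249 with the atrial covariate, 0.867 over genes called in either, and 0.475 to 0.573 without single libraries. The difference in mtDNA share ranged over 22.2 to 26.9 points in Clpp KO against wild type, 20.4 to 23.6 in double KO against Fgf21 KO and 23.0 to 27.6 in double KO against wild type without single libraries. These ranges do not cover leaving out both wild-type replicates 2 and 4, whose lower shares of 25.5% and 28.9% widen the differences from wild type.

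Lists that changed direction did so at these adjusted p-values. In Clpp KO against wild type without wild-type replicates 2 and 4 they were mitochondrial chaperones 0.89, unfolded protein response 0.761 and cardiac stress genes 0.689 (without single libraries 0.00403 to 0.684, turning without replicate 4). In Fgf21 KO against wild type the stress response list changed at 0.67 without both, and ranged from 0.594 to 0.931 without single libraries, turning without wild-type replicate 4 and Fgf21 KO replicates 3 and 4. Interferon-stimulated genes in double KO against Clpp KO changed at 0.963 by ranks, and ranged from 0.0116 (without Clpp KO replicate 1) to 0.916 without single libraries, turning without Clpp KO replicates 2, 3 and 4 and double KO replicates 1 and 2. Chaperones changed at 0.0428 in double KO against Clpp KO and 0.00436 in double KO against Fgf21 KO with the atrial covariate, with 0.195 to 0.955 there without single libraries, turning without Fgf21 KO replicate 4. The mtDNA list in the interaction changed at 5.64e-06 without wild-type replicates 2 and 4, and ranged from 0.0315 to 0.915 without single libraries, turning without wild-type replicate 2.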

Other observations

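The levels of Gdf15 and Hbb-bs were chosen after their values were seen. Gdf15, which encodes a hormone that mitochondrial stress also induces, was at 1.91 ± 0.517 CPM in wild type, 0.792 ± 0.348 in Fgf21 KO, 6.16 ± 0.215 in Clpp KO and 2.36 ± 2.67 in double KO (SD, n = 4 each). The double KO mean rests on replicate 2 at 6.13 CPM, and was 1.1 ± 1.12 without it (SD, n = 3). edgeR with Benjamini-Hochberg gave 2.42 ± 0.61 in Clpp KO against wild type (adjusted p = 0.0636). Haemoglobin Hbb-bs, a sign of blood in the tissue, was at 2440 ± 698 CPM in wild type and 481 ± 138 in Clpp KO, and reached 2860 CPM in 1 double KO library.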
